A study of Zea mays with 6 samples.

How the data were processed

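The series measured where KNOTTED1 (KN1), a homeodomain transcription factor of maize shoot meristems, sits on chromatin in young inflorescences of the inbred line B73. It holds 6 samples: anti-KN1 chromatin immunoprecipitation (ChIP) from tassel primordia (2 samples) and ear primordia (1 sample), and total input DNA matched to each. The second tassel sample is titled for tassels 2 and 3 together and is called tassel replicate 2 here. Whether the tassel samples came from separate plants or harvests is not stated in the labels. Per the labels' protocols, field-grown primordia were fixed in 1% formaldehyde for 10 minutes. Tassel chromatin was sheared to an average of about 400 bp and ear chromatin to about 100 bp. Ear libraries were made with standard adapters and selected on a gel at 150 to 350 bp after 18 cycles of PCR, whereas tassel libraries carried barcoded adapters and skipped the gel. Tissue, fragment size, adapter and gel selection therefore change together between the ear and the tassel libraries.

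The submitters' processing notes name Bowtie and CASAVA, the latter with a version number of 1.4 that may belong to another tool, and the peak names in the files are those written by the peak caller MACS. The aligner's settings, the version of MACS and the genome build are not given in the sources used here. Per the labels, input DNA of each sample was the normalisation control, and each of the 3 ChIP samples has its own peak list. Whether the second tassel list pools reads of several tassels is not given in the sources used here. The 3 inputs were not analysed here. The lists carry no header, and their columns were read from MACS's usual order and checked against the values. The score in the deposited lists is -10 × log10 of MACS's p-value, and no value lies below 50, which corresponds to a p of 1e-05. Many of the best scoring tassel peaks share a score of 3100. Whether that value is a computed p-value is not given in the sources used here. The deposited tag count is the whole number of ChIP tags in the peak. The deposited fold enrichment is the ratio of ChIP to MACS's local background. The last deposited column is a percentage, read as MACS's empirical false discovery rate (FDR) from exchanging ChIP and input. Start and end are printed as the files give them, and end minus start plus 1 equals the given width in every peak. Scores, tags and folds are the authors' values for a peak. They were used to describe, rank or filter peaks within a list, and tags of a region printed for several lists are not compared between them, because depth is unknown. An FDR of 100% would mean that the input gave at least as many peaks as the ChIP at that score.

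All other values were computed from these lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks of different lists were called overlapping when they shared at least 1 bp. Overlapping peaks of the 3 lists were merged into regions, and each region was classed by the lists that contributed a peak. The random level of each overlap came from 1000 circular shifts of 1 list within each chromosome, with the highest peak end of any list standing in for the chromosome's length. Circular shifts keep peak widths, spacing and the number of peaks per chromosome. No sequence was masked in any random placement. Moved peaks may therefore fall where no peak could be called, which would make the folds over random placement too high. For regions in all 3 lists both tassel lists were shifted. Shares are given with 95% Wilson intervals, which cover counting error over peaks only. Neighbouring peaks are not independent, and tags without molecular identifiers are not independent molecules. No p-value is given, because there is 1 ear list and peaks are not replicates. The precision of each list is limited by its tags: the tassel lists hold 87317 and 165023 tags in peaks and the ear list 226165. The total depth of the libraries is unknown from the lists.

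The overlap search was tested on simulated data for the ear list. All 2000 peaks placed on ear peaks among 8000 simulated peaks were found, and 0 of the others were called. The placement set both outcomes in advance, so they check the code and do not measure how well shared sites are found. For uniform lists the shifts gave a mean share of 1.65%, against 1.64% from their coverage. The overlap counts of all 6 ordered pairs of lists equalled those of bedtools 2.31.1 (0 differed). Plots were drawn with matplotlib 3.10.9.

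Before the data were examined, the regions to be named were fixed as the 10 regions in all 3 lists with the best worst rank, the 5 best scoring peaks of each list, and the 5 best ranked regions each of the ear-only class and of the class in both tassel lists but not ear. Ranks follow the score. A score of 3100 was shared by 35 peaks of tassel replicate 1 and 21 of tassel replicate 2, and the rule that such ties were ordered by tags was set after the data were seen. Alternatives fixed then were an overlap of at least 50% of the shorter peak, 400 bp windows around midpoints, the higher scoring 50% of each list, lists of equal length (8876 peaks), the 10 numbered chromosomes only, uniform random placement, a minimum score of 100, and leaving out each tassel list. After the data were seen, an FDR of at most 20%, tassel peaks wider than 500 bp, and random moves of each peak by 0.1 to 1 Mb were added. The planned assignment of peaks to genes, the comparison of fixed gene lists, the position relative to genes and the search for the KN1 sequence motif need the genome of the files' own build and were not analysed here. The only annotation used as a reference was a gene table of assembly Zm-B73-REFERENCE-NAM-5.0, and since no build is named for the lists, none of its coordinates was used. Regions are therefore named by coordinates alone.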

Results

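KN1 is a homeodomain protein of the KNOX class that is present in shoot meristems and keeps them from differentiating. The tassel is the male inflorescence at the tip of the maize plant, and the ear is the female inflorescence on a side branch. Both start as primordia rich in meristems. Regions bound by KN1 were mapped by ChIP-seq in primordia of both, with 2 tassel lists and 1 ear list of peaks called against input DNA. The question the design poses is which regions KN1 occupied in each inflorescence and how far the lists shared them. Genes next to the regions were not analysed here, because no genome build is named for the coordinates.

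KN1 peaks were called at 8876 positions in tassel replicate 1, at 14918 in tassel replicate 2 and at 24737 in the ear. They covered 4795 kb, 8743 kb and 10135 kb, which is under 0.5% of the span of the chromosomes in each list. The median peak held 6 tags in tassel replicate 1, 9 in tassel replicate 2 and 5 in the ear. Tassel peaks had a median width of 500 bp and ear peaks of 322 bp, where tassel chromatin had been sheared to longer fragments. In tassel replicate 1, 92.2% of peaks (95% interval 91.6 to 92.7) and in tassel replicate 2, 80.3% (79.6 to 80.9) were exactly 500 bp wide with the summit at 250 bp, the smallest width in either list. Only 0.198% of ear peaks had that list's smallest width of 200 bp. The FDR column separated the lists further. Its median was 44.7% in tassel replicate 1, 0.28% in tassel replicate 2 and 100% in the ear. The value of 100% was carried by 23788 ear peaks (96.2%), 3709 peaks of tassel replicate 1 (41.8%) and 0 of tassel replicate 2. Read as MACS's FDR, it means that at that score the input gave at least as many peaks as the ChIP, so most ear peaks were not separated from input by this column. Whether ChIP and input of the ear were used in the right roles when its peaks were called was not checked, since the input was not analysed here, and all ear values carry this limit. An FDR of at most 5% was reached by 2 peaks of tassel replicate 1, by 14262 of tassel replicate 2 and by 1 ear peak. The named peaks of tassel replicate 1 with the shared score of 3100 carried 5.41%, just above that limit. An FDR of at most 20% left 3760, 14918 and 140 peaks, and a score of at least 100 left 6721, 13390 and 6206. The FDR did not rise steadily as the score fell. The ear peaks with the 2nd, 3rd and 4th best scores carried 50%, 33.3% and 25%. The limit of 20% thus dropped them while lower scoring ear peaks stayed. In tassel replicate 1 a single peak on chromosome 7 (86238053 to 86239030) held 7158 tags, 8.20% of all tags in peaks of that list, and it had no counterpart in the other lists.

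The comparison of the tassel lists gives the spread between samples of one tissue, which includes the difference in FDR between these lists. KN1 peaks of the tassel lists coincided rarely. Of the peaks in tassel replicate 1, 549 (6.19%, interval 5.70 to 6.71) were overlapped by a peak of tassel replicate 2, and 553 peaks of replicate 2 (3.71%, 3.42 to 4.02) were overlapped by one of replicate 1. The share in replicate 1 was 7.62 times the mean of 0.812% over 1000 circular shifts, none of which went above 1.15%. The summits of overlapping tassel peaks lay a median of 215 bp apart (quartiles 93 to 368). Overlap itself limits such distances. No random level was computed for them here or for the ear, so they are not evidence of a shared site. Among tassel peaks wider than 500 bp, 20.03% of the 694 in replicate 1 (interval 17.2 to 23.2) were overlapped by the 2946 such peaks of replicate 2.

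Across tissues, the ear list shared far more with tassel replicate 2 than the tassel lists shared with each other. The ear list overlapped 3352 peaks of tassel replicate 2, or 22.5% (21.8 to 23.1), which was 19.0 times the mean of the shifts (1.18%, highest 1.49%). It overlapped 714 peaks of tassel replicate 1, or 8.04% (7.496 to 8.63), 7.11 times the mean of the shifts (1.13%, highest 1.48%). In the other direction, 14.0% of ear peaks (13.6 to 14.5) lay on peaks of tassel replicate 2 and 2.95% (2.74 to 3.17) on peaks of tassel replicate 1. Summits lay a median of 156 bp apart between ear and tassel replicate 2 (quartiles 67 to 266) and 200 bp between ear and tassel replicate 1 (99 to 307). With each list held to its 8876 best scoring peaks, the share in the ear list was 15.6% for tassel replicate 2 and 5.15% for tassel replicate 1, and 4.16% of replicate 2 lay in replicate 1. In these shares the ear list thus stood no further from either tassel list than the tassel lists stood from each other. For tassel replicate 1 this order depended on the measure. Over all its peaks the fold over the shifts was 7.62 in tassel replicate 2 and 7.11 in the ear. Of its peaks wider than 500 bp, 26.8% (23.6 to 30.2) lay on any peak of tassel replicate 2 and 25.2% (22.1 to 28.6) on ear peaks. With 1 ear list, a difference between tissues cannot be tested across samples. The tassel lists held 2 and 14262 peaks at an FDR of at most 5%, and 3760 and 14918 at an FDR of at most 20%. Their low overlap is therefore not a measure of variation between tassels alone, and a difference between ear and tassel stays open. With an FDR of at most 20% in every list, only 140 ear peaks remained, which caps the share of either tassel list that they can overlap. They were not simply the best scoring ear peaks, since the 2nd to 4th best had a higher FDR and were dropped. Of these 140, 92.1% (86.5 to 95.6) lay on peaks of tassel replicate 2 and 17.1% (11.8 to 24.2) on peaks of tassel replicate 1 that passed the same limit.

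**Figure D1:**
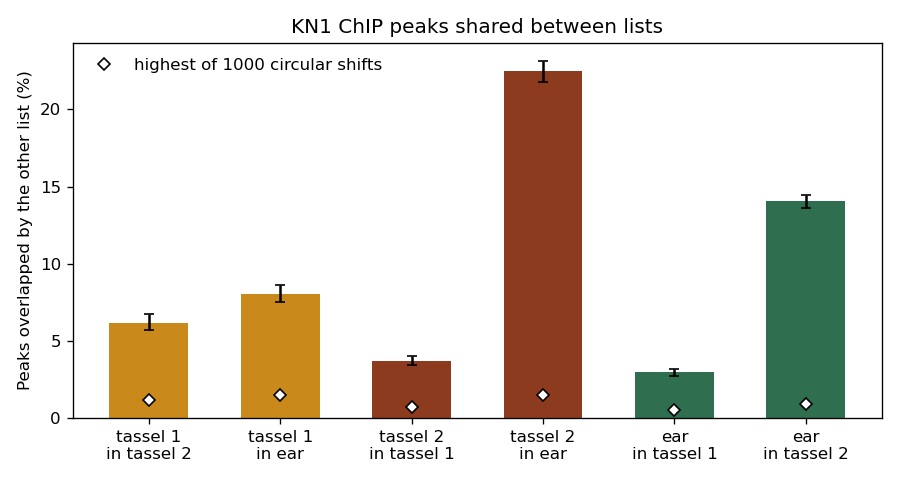
Share of KN1 ChIP peaks of one list (first name) overlapped by at least 1 bp by a peak of another list, in percent. Bars give the share, error bars the 95% Wilson interval over peaks and open diamonds the highest of 1000 circular shifts; tassel replicate 2 in ear is highest at 22.5%, and every bar lies above its diamond.

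The ear peaks with the highest scores were the ones most often found in the tassel. In the highest quintile of ear scores (111 and above), 39.5% of peaks (38.2 to 40.9) were overlapped by tassel replicate 2 and 7.64% (6.93 to 8.41) by tassel replicate 1. In the lowest quintile the shares were 5.92% (5.30 to 6.61) and 1.35% (1.07 to 1.72). Of the 140 ear peaks at an FDR of at most 20%, 129 (92.1%, 86.5 to 95.6) lay on peaks of tassel replicate 2 and 40 (28.6%, 21.7 to 36.5) on peaks of tassel replicate 1. Of the 23788 ear peaks at an FDR of 100%, 2803 (11.8%, 11.4 to 12.2) lay on peaks of tassel replicate 2 and 586 (2.46%, 2.27 to 2.67) on peaks of tassel replicate 1. The size of the rise in the ear depended on the ranking. From the lowest to the highest quintile, the share overlapped by tassel replicate 2 went from 2.18% to 44.6% by tags. By fold enrichment it went from 12.2% (11.3 to 13.1) to only 20.8% (19.7 to 21.9). In tassel replicate 2 even the direction depended on how peaks were ranked. By score, 20.8% (19.4 to 22.3) of the highest quintile and 25.1% (23.6 to 26.7) of the lowest quintile were overlapped by the ear list. By tags, the share went from 15.2% (13.9 to 16.5) in the lowest to 37.6% (35.9 to 39.4) in the highest quintile. By width, 64.7% (63.0 to 66.4) of the peaks of tassel replicate 2 wider than 500 bp lay on ear peaks, against 12.1% (11.5 to 12.7) of those exactly 500 bp wide. In tassel replicate 1 the same shares were 25.2% (22.1 to 28.6) and 6.59% (6.07 to 7.15).

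**Figure D2:**
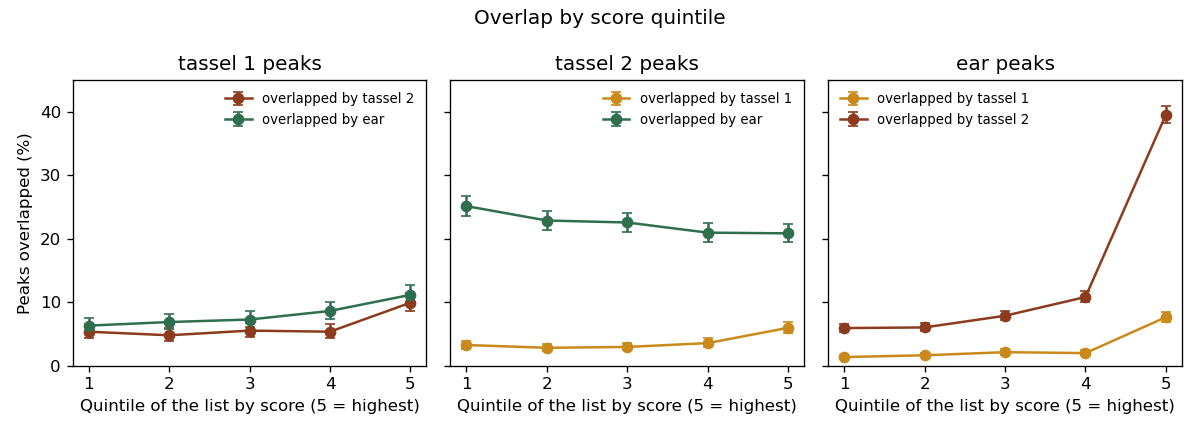
Share of peaks overlapped by each other list (y axis, percent) by quintile of the list's own scores (x axis, 5 is highest), for tassel replicate 1, tassel replicate 2 and ear, with 95% Wilson intervals. The overlap of ear peaks with tassel replicate 2 goes from 5.92% in the lowest to 39.5% in the highest quintile, while tassel replicate 2 peaks in the ear list go from 25.1% to 20.8%.

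Merging the 3 lists gave 44066 regions, of which 330 held a peak of every list. Shifting the tassel lists gave 1.31 such regions on average and at most 6. Shifting both also removes the overlap of ear and tassel replicate 2, so this level is lower than one that keeps it. Without tassel replicate 1, 3343 regions were called in ear and the remaining tassel list, and without tassel replicate 2 there were 714, where a region needs a peak of only 2 lists. The region on chromosome 4 from 156340971 to 156342529 ranked 12th, 7th and 15th in tassel replicate 1, tassel replicate 2 and ear, with 266, 276 and 74 tags. The region on chromosome 5 from 54214211 to 54215332 held 208, 272 and 79 tags. The region on chromosome 8 from 9419990 to 9421141 held 198, 271 and 66 tags, and its enrichment over background in the ear, 963-fold, was the highest in that list. The region on chromosome 1 from 168908320 to 168909508 was the best scoring ear peak, at 122 tags, and held 170 and 310 tags in the tassel lists. The others of the first 10 lay on chromosome 2 (48392329 to 48393925, 67598953 to 67600101 and 152196242 to 152197319), on chromosome 7 (53725811 to 53726992 and 35181738 to 35183253) and on chromosome 5 (118614903 to 118616089). The last of these held the best scoring peak of tassel replicate 1, with 132 tags there, 111 in tassel replicate 2 and 38 in the ear. Tag numbers are given for each list on its own, since the depths of the libraries are unknown.

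The best scoring peak of tassel replicate 2, on chromosome 9 from 47122161 to 47123264, had the second best score of tassel replicate 1 and ranked 566th in the ear. Many of the best scoring tassel peaks shared the score of 3100 and were ordered by tags. In tassel replicate 1 the peak with 7158 tags and a 5810-fold enrichment scored 3100. Peaks of 132 tags (1607-fold) and 141 tags (710-fold) scored above it. Best therefore means best scoring here, which need not be strongest. Of the 5 best peaks, 4 in tassel replicate 1, 4 in tassel replicate 2 and 3 in the ear lay in regions called in all lists. In tassel replicate 1 these included regions on chromosome 9 (131252262 to 131259235) with 1738 tags and on chromosome 5 (38937337 to 38939432) with 872 tags, which ranked 2800th and 4432nd in the ear list. Their ear peaks held 9 and 7 tags at an FDR of 100%. In tassel replicate 2 they included chromosome 4 from 62020370 to 62021676 with 373 tags and chromosome 9 from 95737882 to 95740167 with 343 tags. The latter ranked 3414th in tassel replicate 1, with 14 tags, and 2914th in the ear, at an FDR of 100%. The second best peak of tassel replicate 2, on chromosome 5 from 66107299 to 66108275, held 2930 tags and was in no other list. In the ear, the second best peak lay on chromosome 3 (53142271 to 53143294, 148 tags) and was found in both tassel lists. The third (chromosome 7, 175557821 to 175560036, 138 tags) and the fifth (chromosome 9, 151979109 to 151981023, 141 tags) were found in tassel replicate 2 but not in tassel replicate 1.

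Regions called in the ear alone held fewer tags than those shared with the tassel. Ear-only regions numbered 20856, with a median of 5 tags, against a median of 15 ear tags in the 3015 regions shared by ear and tassel replicate 2 alone and 23 in regions of all 3 lists. Of the ear-only regions, 98.8% had an FDR of 100% and 9 an FDR of at most 20%. Over all 24737 ear peaks these were 96.2% and 140. The best ranked of them stood 71st in the ear list, on chromosome 8 from 160988069 to 160988651, with 51 tags. The next lay on chromosome 6 (95069443 to 95069867, 59 tags, and 97320717 to 97321514, 68 tags), on chromosome 7 (129366470 to 129367348, 73 tags) and on chromosome 3 (214835891 to 214836891, 75 tags). Regions in both tassel lists but not in the ear numbered 241, against 71.1 on average and at most 97 after shifts. The best ranked was on chromosome 6 from 83438836 to 83439812, with 50 and 51 tags in tassel replicates 1 and 2. It was followed by chromosome 1 (48108386 to 48111641, 183 and 31 tags), chromosome 8 (44141744 to 44142735, 50 and 58 tags), chromosome 3 (4042528 to 4043504, 31 and 34 tags) and chromosome 9 (153161106 to 153162087, 70 and 47 tags). These classes are not a test of tissue, because 7908 regions were called in tassel replicate 1 alone and 11319 in tassel replicate 2 alone.

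KN1 peaks were spread over all 10 numbered chromosomes at similar density but lay more often towards the chromosome ends. The ear list held from 11.1 peaks per Mb on chromosome 10 to 12.6 on chromosome 1, tassel replicate 2 from 6.61 on chromosome 4 to 7.76 on chromosome 1, and tassel replicate 1 from 3.99 on chromosome 7 to 4.62 on chromosome 5. The outermost parts of the chromosomes, together 40% of their length, held 50.8% of ear peaks (50.2 to 51.4), 50.9% of tassel replicate 2 peaks (50.1 to 51.7) and 46.1% of tassel replicate 1 peaks (45.1 to 47.1). The share was above 40% on 10 of 10 chromosomes in each list. Regions shared by ear and tassel replicate 2 but not tassel replicate 1 lay there in 61.6% of cases (59.9 to 63.3), against 48.9% (48.2 to 49.6) of ear-only regions and 47.8% (46.8 to 48.7) of regions in tassel replicate 2 alone. The other shared classes leaned the same way. The share was 57.0% (51.6 to 62.2) in all 3 lists and 56.7% (51.8 to 61.5) in tassel replicate 1 and ear alone. In both tassel lists without ear it was 54.8%, with a wide interval (48.5 to 61.0). Peaks of tassel replicate 2 wider than 500 bp lay there in 59.0% of cases (57.3 to 60.8) and those of 500 bp in 48.9% (48.0 to 49.8). In tassel replicate 1 the intervals of the same shares overlapped, at 48.3% (44.6 to 52.1) and 45.9% (44.8 to 47.0). The division into outer and inner parts of the chromosomes was chosen after the data were seen, and the highest peak end stood in for the chromosome length. Sequence in which no peak could be called was not accounted for, and the inputs were not analysed here. The lean towards the ends is therefore not shown to be a trait of KN1 binding.

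**Figure D3:**
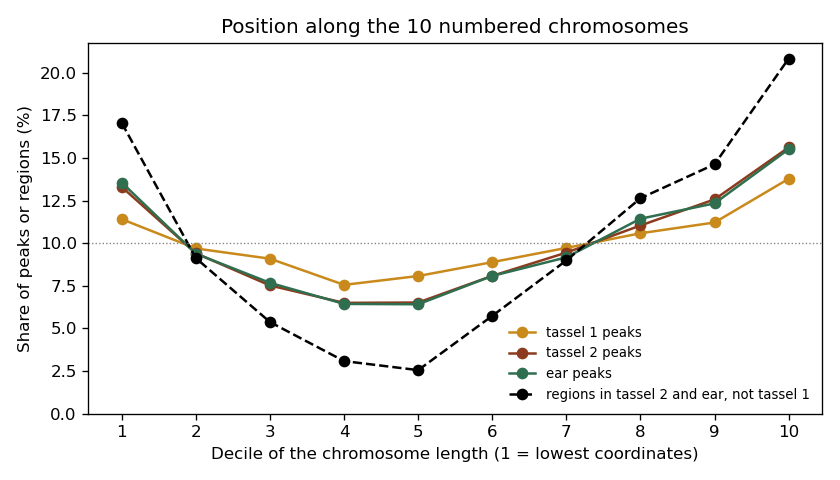
Share of peaks or regions (y axis, percent) in each decile of the length of the 10 numbered chromosomes (x axis, 1 is the lowest coordinates), for the 3 lists and for the 3015 regions in tassel replicate 2 and ear but not tassel replicate 1. The dotted line marks 10%, the share of an even spread; deciles 4 to 6 hold 24.5% of tassel replicate 1 peaks, 20.9% of ear peaks and 11.4% of the shared regions.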

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

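Peaks on organelle sequence are outside the nuclear comparison and are given because their number exceeded the 3 that a count of 0 allows; the inputs, which would show the background there, were not analysed here. Mitochondrial sequence carried 6 peaks in tassel replicate 1 and 11 in tassel replicate 2, against 1 in the ear. Plastid sequence carried 10 peaks in the ear, against 1 in each tassel list. Of the ear's organelle peaks, 0 were overlapped by a peak of either tassel list, and leaving out all sequences other than the 10 numbered chromosomes left 330 regions in all 3 lists.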

How the results depend on the processing

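The filters on FDR and on tassel peak width, and the moves of 0.1 to 1 Mb, were chosen after the data were seen. Of 68 alternative values, 30 stayed within the 95% interval or the range of shifts of the reported one or, for a count, within 1.5 times of it, and 38 moved. The share of tassel replicate 1 in replicate 2 (6.19%) became 4.73% with an overlap of 50% of the shorter peak, 4.81% with 400 bp windows, 4.73% in the higher scoring 50%, 4.12% at equal list sizes, 7.53% at an FDR of at most 20% and 20.03% for tassel peaks wider than 500 bp. In the same order, the share of tassel replicate 1 in ear (8.04%) became 6.13%, 7.02%, 7.35%, 5.15%, 0.638% and 25.2%, and that of tassel replicate 2 in ear (22.5%) became 19.7%, 20.2%, 17.8%, 15.6%, 0.865% and 64.7%. Tassel replicate 2 stayed above tassel replicate 1 in its share of ear overlap in the settings other than the FDR limit. The FDR limit dropped the 2nd to 4th best scoring ear peaks, so it did not simply keep the best of that list. At an FDR of at most 20% the 140 ear peaks left cap both shares, so those values do not bear on the order. Of these ear peaks, 92.1% (86.5 to 95.6) lay in tassel replicate 2 and 17.1% (11.8 to 24.2) in tassel replicate 1. With moves of 0.1 to 1 Mb as the random level, the fold over random placement in ear was 6.56 for tassel replicate 1 (from 7.11) and 16.3 for tassel replicate 2 (from 19.0). The 330 regions in all lists became 136 in the higher scoring 50%, 209 at equal list sizes, 23 at an FDR of at most 20% and 108 for wide tassel peaks, and ranged from 714 to 3343 with a tassel list left out, where by construction only 2 lists need a peak. Ear-only regions (20856) became 10812 in the higher scoring 50%, 7208 at equal list sizes and 10 at an FDR of at most 20%. Regions in both tassel lists but not ear (241) became 77 in the higher scoring 50% and 31 for wide tassel peaks, and regions of the remaining tassel list without ear ranged from 8162 to 11566. A minimum score of 100 left 6206 ear peaks, and an FDR of at most 20% left 3760 peaks in tassel replicate 1 and 140 in the ear. The highest score quintile of the ear in tassel replicate 2 became 34.7% with 400 bp windows (from 39.5%). The ratio of the densest to the sparsest chromosome in the ear became 1.23 in the higher scoring 50% (from 1.14). Fewer peaks in a list leave fewer to overlap; other causes of these moves were not tested. No paired analysis was possible because the overlaps come from no test across samples, and the tassel samples that share replicate numbers are a ChIP and its input. Genes bound in all lists, position relative to genes, gene lists and the motif, with their other distance limits, gene assignment, matching and motif settings, were not run, because no genome of the lists' build was used here. The low number of tags per peak, a median of 5 to 9, limits all lists.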

Other observations

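The tests of minimum-width peaks, of tags at 1 position and of random positions, the moves of 0.1 to 1 Mb, and the clusters and ranks in the first paragraphs, were chosen after the data were seen.

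Regions called in both tassel replicate 2 and ear came in clusters. Of 3345 such regions on the numbered chromosomes, 645 (19.3%) had another within 10 kb, in 304 clusters. Moving each region by 0.1 to 1 Mb, which keeps the regional density, gave 5.79% on average and at most 7.504% over 100 draws. With regions up to 1 kb apart joined first, 16.0% of 3278 lay in clusters, against 4.53% on average and at most 5.94%. The 5 clusters with 4 regions each lay on chromosome 1 (52085915 to 52095852), chromosome 2 (5505860 to 5517028), chromosome 3 (3470570 to 3480467 and 230513974 to 230528018) and chromosome 8 (162539909 to 162552948). The cluster at 3470570 on chromosome 3 held 2 regions that were called in all 3 lists. Clusters of 4 regions also appeared among the random draws.

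The best ranked regions of all 3 lists were placed differently along the chromosomes from the rest. Of the 66 with the best worst ranks, 39.4% (28.5 to 51.5) lay in the outermost parts that make up 40% of chromosome length, against 61.4% (55.4 to 67.0) of the other 264. Of the first 10, 2 lay there. No explanation was tested.

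The first pattern that a reader may want to follow is that tassel replicate 2 shared more peaks with the ear than tassel replicate 1 did. Unequal list lengths were argued against as the whole cause, since at equal lengths the shares were 15.6% (14.8 to 16.4) and 5.15% (4.71 to 5.63). Minimum-width peaks in replicate 1 are not the whole cause either. Among wider peaks the shares were 64.7% and 25.2%, and among 500 bp peaks 12.1% and 6.59%. Replicate 1 held more 500 bp peaks (92.2% against 80.3%), so a part played by width was not excluded. Tissue of origin as the factor that orders the lists would put the tassel lists together, yet at equal lengths 4.16% (3.76 to 4.59) of replicate 2 lay in replicate 1 against 15.6% in the ear. Of replicate 1, 4.12% (3.73 to 4.56) lay in replicate 2 against 5.15% in the ear. In these shares the lists were thus not ordered by tissue, but this cannot decide whether KN1 binding differs between tissues. For replicate 1 the fold over the shifts had the other order, 7.62 (7.02 to 8.26) in replicate 2 and 7.11 (6.63 to 7.63) in the ear, with overlapping intervals. Fragment size, adapter and gel selection change with tissue. In addition, only 2 peaks of replicate 1 reached an FDR of at most 5%, against 14262 of replicate 2. At an FDR of at most 20% these numbers were 3760 and 14918. Weak sites missed in replicate 1 stay open: of the regions in tassel replicate 2 and ear, 20.3% (17.5 to 23.5) of the quintile with the most tassel tags were also in replicate 1, against 7.77% (5.98 to 10.1) of that with the fewest, but the quintiles between held 5.98% to 9.12%, without a gradual rise. Differences between the tassel collections were not tested.

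The second pattern is that tassel peaks of exactly 500 bp lay on ear peaks less often than wider ones. Chance overlap of wider peaks is not the whole cause, since as 400 bp windows the shares in replicate 2 were 57.2% (55.4 to 59.0) and 11.1% (10.6 to 11.7). Fewer tags are not either, since at matched tag numbers (2501 peaks of each kind, median 12 tags) they were 61.8% (59.9 to 63.7) and 10.5% (9.37 to 11.8). Tags at 1 position, such as copies of the same fragment from PCR, may give the smallest width and a centred summit, and 0 of 20154 tassel peaks of 500 bp had a summit elsewhere. Without the reads this cannot be told apart from a minimum width set by the peak caller, and no biological explanation was tested.

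The third pattern is that ear peaks at an FDR of 100% were still found in tassel replicate 2, at 11.8% (11.4 to 12.2), though in tassel replicate 1 at only 2.46% (2.27 to 2.67). For tassel replicate 2, random positions would give at most 0.912% over 1000 circular shifts, and regional peak density at most 1.04% over 1000 moves of 0.1 to 1 Mb. No sequence was masked in these placements. They do not account for sequence in which no peak can be called, so the random level may be too low. Part of these peaks may mark recurrent sites that the FDR column does not separate, as a hypothesis. KN1 binding common to ear and tassel, and chromatin that is recovered in any ChIP, both stay open, because the inputs were not analysed here.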
